A study of Mus musculus with 2 samples.

How the data were processed

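Hippocampal RNA from male ICR offspring, pooled by group, was measured on 1 array for the control group and 1 for the glyphosate group. Per the labels' protocols, total RNA was digested with RNase R, amplified with random priming into Cy3-labelled cRNA and hybridised to a circRNA array in 1 colour. The number of offspring in each pool is not given in the sources used here. Per the file headers, images were read with Agilent Feature Extraction 11.0.1.1 under a protocol for 1-colour arrays, with mm9 as the genome build of the array design. The deposited processed signals are intensities on a linear scale, which per the file headers were corrected for background by Feature Extraction and not scaled between arrays. The authors also deposited a table of log2 values for the 14236 circRNAs. The submitters' processing notes name Agilent Feature Extraction and limma, without a normalization method. The table's medians were 6.69 for both arrays and its maxima 17.44 for both. It was therefore read as log2, normalized between the arrays and not centred by circRNA. Its ranks followed the median spot signal without background subtraction (Spearman rho 0.9996 and 0.9997 across circRNAs). They followed the processed signals nearly as closely (0.9987 and 0.9994), so ranks say little about subtraction. Its lowest values were 4.03 and 4.13 in log2, while the lowest processed circRNA signals were 1.21 and 1.43 before log2. Its exact method remains unknown.

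The log2 of each processed signal was taken and the 75th percentile over all non-control probes of the array subtracted, since more than 50 percent of the probes were well above background. Control spots were left out, as were spots marked as outliers for non-uniformity or within their population (21 circRNA spots on the control array and 8 on the glyphosate array). This left 14211 circRNAs with a usable spot on both arrays. Spots of the same probe were averaged. A probe was counted as detected where the scanner software called it well above background, for repeated probes on every usable spot. The choice of signal can alter the spread of the ratios: across circRNAs the SD of log2 ratios was 0.61 with the processed signals and 0.43 with the median spot signals after normexp correction, an offset of 50 and the same scaling, a setting that changes several steps together.

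With 1 array per group, circRNAs were counted by fold size, at 1.5-fold and 2-fold, and no test was run. Precision was limited by that number of arrays. Feature Extraction gave a median error of 0.21 for a log2 ratio, and the SD of a log2 ratio of single spots had a median of 0.14 over the 66 repeated probes detected on every spot. That SD, and the SDs between spots given below for single probes, were taken after spots marked as outliers were left out, which can lower them. These errors are technical and within an array. A bound for a circRNA detected on 1 array was the bright array's value over the higher of the dim value and the lowest signal well above background on the dim array, after scaling.

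The rule for named circRNAs was fixed before the data were examined. It took the 12 largest folds in each direction among circRNAs detected on both arrays with the same direction in every normalization, the 3 largest bounds in each direction among those detected on 1 array, and the 5 brightest of the control array. Of these, at most 2 identifiers in each direction are printed, and the others are summarised. Host genes, circRNA classes and chromosomes were not paired with the probes in the sources used here, so the lists of host genes, the classes and the circRNAs that share a host gene were not analysed here. The 17 gene lists were set against the mRNA probes instead, a use not planned beforehand. Transcript identifiers of the mRNA probes were matched without version to a RefSeq table of assembly GRCm38.p6, used for names only: 44 of 50 matched 1 gene, 0 matched several and 6 matched none. The value of 1 mRNA probe is not reported here.

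Alternatives fixed before the data were examined were the percentile over probes detected on both arrays, quantile normalization, equal medians of detected circRNAs, cyclic loess, normexp with percentile scaling or with quantiles, the authors' processed values, other filters on detection, outlier spots kept, the median of spots, and another detection call. The mean spot signal planned for normexp was not a column of the files, so the median spot signal took its place. Scaling to bright corner spots, a shared signal floor, the counts of mRNA probes and the counts past 8-fold were added after the data were seen.

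The percentile scaling and the counts were tested on simulated arrays of 14309 probes with the noise of repeated spots and 200 circRNAs altered by known folds, 50 of each size. Past 2-fold in the right direction were 100% of those altered 4-fold, 100% of those altered 8-fold and 62% of those altered exactly 2-fold, which lie on the threshold. Of those altered 1.25-fold 0% passed, and of 12386 unaltered circRNAs 0.258% passed in either direction. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.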

Results

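Circular RNAs (circRNAs), closed RNA loops formed by back-splicing, were profiled in the hippocampus of male mice of the outbred ICR strain at postnatal day 28. Their mothers had been exposed to a glyphosate-based herbicide. Pregnant mice, 8 per group, drank either purified water or water holding 0.38% glyphosate (1% Roundup), which amounted to 50 mg of glyphosate per kg per day. Total RNA of the offspring was pooled by group, digested with RNase R, which degrades linear RNA, and hybridised to 1 array per group. There were no replicates, so no test, p-value or error between animals could be given, and every difference below describes these 2 arrays. The arrays also differed in scan day and in position on the slide, so batch and group could not be told apart.

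Of 14236 circRNA probes, each printed as 1 spot, 12736 (89.6%) were well above background on the control array and 13044 (91.7%) on the glyphosate array. With the same signal floor applied to both arrays after scaling, the numbers were 12815 and 12793. The glyphosate array was brighter by 1.49-fold at the 75th percentile of signal (303.3 against 203.7), a difference removed by scaling each array to that percentile. The 10 brightest circRNAs held 15.9% of circRNA signal on the control array and 12.7% on the glyphosate array, and no circRNA spot was saturated.

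The comparison of the 2 arrays asked whether glyphosate exposure of the mothers went with altered circRNA levels in the hippocampus of the offspring. Among 12586 circRNAs well above background on both arrays, 518 were at least 2-fold higher and 579 at least 2-fold lower on the glyphosate array, together 8.72%. At 1.5-fold, 1389 were higher and 1625 lower, and the remaining 76.1% lay within 1.5-fold. The log2 ratios had a median of -0.02 and an SD of 0.61 across circRNAs. Scaling each array to its own percentile holds that median near 0, so a shift shared by most circRNAs could not be seen. The log2 signals of the arrays correlated across circRNAs at Pearson r = 0.960, with the caution that circRNAs are not independent replicates.

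The spread of repeated spots within an array, applied to unchanged circRNAs in 1000 simulations, gave a mean of 28.1 circRNAs past 2-fold and at most 48, against the 1097 observed. This noise holds only differences between spots of the same array, and leaves out differences between animals, pools, labelling reactions and scans. The numbers past 2-fold were 208 higher and 209 lower after normexp correction of the median spot signal with percentile scaling, and 313 and 319 in the authors' processed values. The share of 2-fold differences that were higher was 47.2%, and 80.2% when the arrays were scaled to their bright corner control spots, a choice added after the data were seen that rested on 5 and 11 spots.

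**Figure D1:**
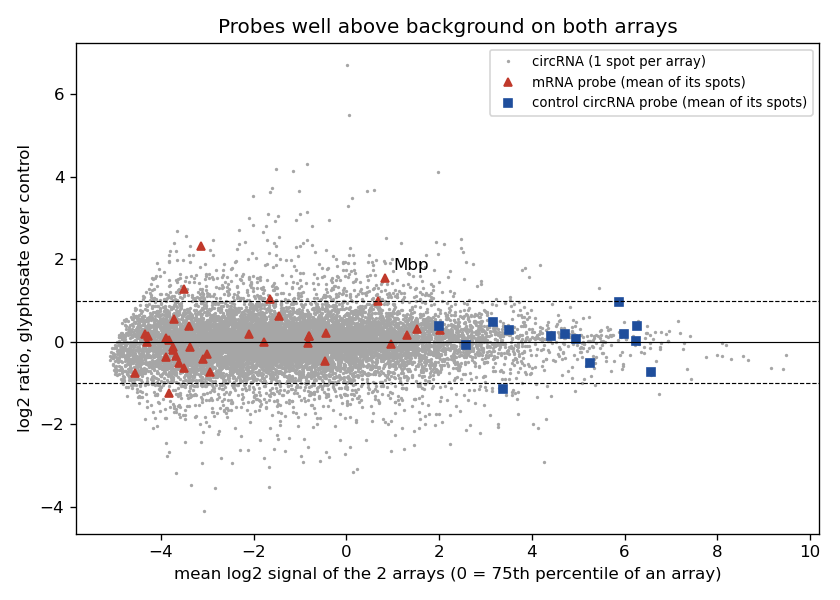
Log2 ratio of glyphosate over control (vertical axis) against the mean log2 signal of the 2 arrays (horizontal axis, 0 at the 75th percentile of an array). Grey points are the 12586 circRNAs well above background on both arrays, red triangles the 36 mRNA probes and blue squares the 14 control circRNA probes with every spot well above background, and dashed lines mark 2-fold; 518 circRNAs lie on or above the upper line and 579 on or below the lower.

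The circRNAs are given by probe identifier, since the files and tables used here do not pair them with host genes. The circRNA with the largest fold higher, ASCRP4000332, had a signal of 20.0 on the control array and 3117 on the glyphosate array, a 104.5-fold difference after scaling. ASCRP4007596 followed, with signals of 31.7 and 2135 and a 45.2-fold difference. Over the normalizations fixed before the data were examined, their smallest folds were 30.8 and 17.7. The 12 circRNAs with the largest folds higher ranged from 11.6-fold to 104.5-fold (5.92-fold to 57.7-fold in the authors' processed values), and the 12 with the largest folds lower from 7.54-fold to 17.3-fold (2.79-fold to 7.94-fold). Over the normalizations fixed beforehand, the smallest fold of any of these was 3.18 among the higher and 1.83 among the lower, and the circRNA at 17.3-fold came down to 2.47-fold. Dim-array signals ran from 14.9 to 193.8 (control array) for the higher set and from 7.88 to 2118 (glyphosate array) for the lower. Some lay below MM9NEGATIVE016, a probe named as negative that passed the same detection call at 15.7 and 22.4. Folds resting on those signals are open to the low signal.

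A further 146 circRNAs were well above background on the control array only and 441 on the glyphosate array only. These numbers depend on the floor of each array, which after scaling was lower on the glyphosate array (log2 -5.42 against -5.05). With a shared floor, 12815 and 12793 were detected on the control and glyphosate arrays. For each circRNA a bound was computed from the higher of the dim array's own signal and the lowest signal well above background there. Some glyphosate-only bounds lay below 1-fold, down to 0.77, and set no direction. ASCRP4002683 was at least 90.5-fold lower on the glyphosate array and ASCRP4002684 at least 80.5-fold lower. Their control signals were 431.6 and 384.1, and their glyphosate signals of 1.57 and 1.49 stood beside a median of 1.504 for the structural negative spots of that array. In the authors' processed values the pair was 26.5-fold and 25.2-fold lower. The third-largest bound on that side was 61.3-fold and the next 9.37-fold. The largest bound in the other direction was 10.2-fold. At least 2-fold over the floor were 62 of the control-only and 66 of the glyphosate-only circRNAs.

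The 5 brightest circRNAs of the control array, with signals from 85570 to 173847 there and from 100676 to 192435 on the glyphosate array, had log2 ratios between -0.66 and -0.32. In 2 of them the difference reached 1.5-fold. In the authors' processed values their log2 ratios lay between -0.15 and 0.26. Those values have the same maximum of 17.44 on both arrays, which can hold the ratios of the brightest circRNAs near 0. They therefore cannot decide the direction, which was not settled.

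The array also carried 50 probes designed on mRNAs, each printed as 10 spots, and 44 of them matched a gene symbol. These probes became known as mRNA probes only once the files were read, and the genes below were chosen after their values were seen. Mbp, which encodes myelin basic protein, a main structural protein of myelin in the central nervous system, was 2.92-fold higher on the glyphosate array (log2 ratio 1.55, SD between spots 0.08). Gpi1, which encodes the glycolytic enzyme glucose-6-phosphate isomerase, was higher by a log2 ratio of 1.00 (SD 0.07). Chgb, encoding the secretory granule protein chromogranin B, was 2.04-fold higher (log2 ratio 1.03, SD 0.10). Trp53rka was 2.38-fold lower (log2 ratio -1.25, SD 0.18).

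In all, 36 mRNA probes were well above background on every usable spot of both arrays. Of these, 6 were at least 1.5-fold higher, 4 at least 1.5-fold lower and 26 within 1.5-fold. Their log2 ratios had an SD of 0.68 across probes, beside the SDs between spots above, which are technical. Among circRNAs detected on both arrays, 23.9% were at least 1.5-fold apart in either direction. Besides Mbp, Gpi1 and Chgb, the higher probes were Ppara, a nuclear receptor gene of fatty acid oxidation (log2 ratio 1.28), Lhfp (0.62), and a transcript with no gene symbol (2.32). Besides Trp53rka, the lower probes were Tm9sf1 (-0.75), Atg3, which encodes a conjugating enzyme of autophagy (-0.74), and Taf1a (-0.65). Mbp signal was 213.2 on the control array and 927.9 on the glyphosate array, and Gpi1 signal was 232.2 and 692.3. Ppara was dim, at 11.5 and 41.6.

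Mbp and Gpi1 stayed past 1.5-fold under every alternative tried, with log2 ratios of 1.35 to 1.88 for Mbp and 0.86 to 1.33 for Gpi1. After normexp correction and percentile scaling these were the only 2 probes left at 1.5-fold higher, and Trp53rka, at -0.64, was the only 1 left lower. Under the alternatives the log2 ratio came as low as 0.56 for the transcript with no gene symbol, 0.08 for Ppara, 0.46 for Chgb and 0.25 for Lhfp, and as near to 0 as -0.31 for Trp53rka, -0.12 for Tm9sf1, -0.23 for Atg3 and -0.16 for Taf1a. Whether a probe read linear mRNA left after RNase R or circular RNA with the same sequence was not determined.

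Among the mRNA probes within 1.5-fold, Apoe, the gene of the lipid carrier apolipoprotein E, had a log2 ratio of 0.31. Actb, which encodes cytoplasmic beta-actin, had 0.17, H2-Q7, a class I histocompatibility gene, 0.21, and Gamt, which encodes an enzyme of creatine synthesis, 0.13. Lhx1 (-0.02), Pex11a (-0.05) and Il2 (-0.12) lay near 0. E2f1, a transcription factor gene of the cell cycle, had -0.50. Il2 (16.0 on the control array and 22.0 on the glyphosate array) and E2f1 (19.8 and 20.8) were dim. They lay near MM9NEGATIVE016 (15.7 and 22.4) and MM9NEGATIVE017 (18.1 and 24.8), 2 probes named as negative but well above background on every spot. Of the remaining 14 mRNA probes, which were not well above background on some spots, 5 were not so on any spot of either array.

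**Figure D2:**
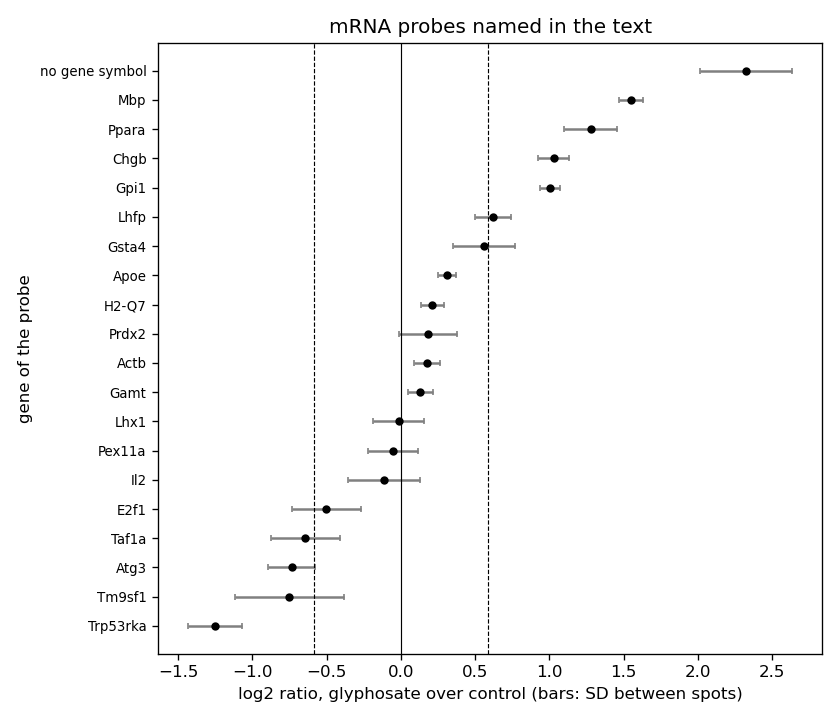
Log2 ratio of glyphosate over control (horizontal axis) for the mRNA probes named in the text with every usable spot well above background, and the transcript with no gene symbol that was past 1.5-fold, 1 row per probe. Points are differences of the means over spots, bars the SD of a ratio of single spots, which is technical, and dashed lines mark 1.5-fold; Mbp lies at 1.55 and Trp53rka at -1.25.

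Of 17 gene lists fixed before the data were examined, 3 had a member among the mRNA probes. Mbp was the only oligodendrocyte marker on a probe. In the list of oxidative stress and mitochondria, Gsta4, which encodes a glutathione transferase acting on lipid peroxidation products, had a log2 ratio of 0.56, and Prdx2, which encodes a peroxide-reducing enzyme, 0.18. Neither reached 1.5-fold, but over the normalizations Gsta4 ranged from -0.18 to 0.89 and Prdx2 from -0.08 to 0.51, with both negative after normexp with percentile scaling. Gsta4 passed 1.5-fold under several alternatives, among them quantile normalization (0.591), cyclic loess (0.594) and bright corner scaling. Its signals were low, at 12.7 on the control array and 27.9 on the glyphosate array. In the list of the GABAergic synapse, the receptor subunit gene Gabrg1 was well above background on 4 of 9 control spots and 10 of 10 glyphosate spots, with a log2 ratio of 0.42 that is open to the low signal.

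The 14 control circRNA probes of the array design, whose targets the files do not name, had log2 ratios from -1.16 to 0.96 with an SD of 0.54. Of these, 1 was at least 1.5-fold higher and 2 at least 1.5-fold lower.

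In the authors' processed values, over all 14236 circRNAs, 330 were at least 2-fold higher and 336 at least 2-fold lower. Their sum of 666 stood beside the 663 differentially expressed circRNAs that the study states. The 666 was counted without a filter on detection, and whether the study counted by the same criteria was not determined. Of the circRNAs past 2-fold after percentile scaling, 310 higher and 314 lower were also past 2-fold in the same direction in the authors' values, and 0 were past it in opposite directions.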

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

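All values in this part are from probes outside the comparison and were looked at after the data were seen. Of 15 probes of the array design named as negative, 2 were well above background on every spot of both arrays. The mean signal of MM9NEGATIVE016 was 14.9 times the median of the structural negative spots on the glyphosate array and 11.7 times on the control array. That of MM9NEGATIVE017 was 16.5 and 13.4 times. Their log2 ratios after scaling were -0.07 and -0.12, so both arrays showed the signal at about the same relative level.

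Of the E1A spike-in probes, 3 were well above background on every spot of both arrays. Others were not so on any spot, such as E1A_r60_1 (0 of 18 control spots and 0 of 20 glyphosate spots). Whether the signals came from spike-in RNA was therefore not determined. The mean signal of E1A_r60_3 was 110.2 times the median of the structural negative spots on the glyphosate array and 68.1 times on the control array. That of E1A_r60_a22 was 20.3 and 11.7 times, and that of E1A_r60_a107 was 9.38 and 14.1 times, higher on the control array.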

How the results depend on the processing

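The scaling to bright corner spots, the shared floor and the mRNA probe counts were chosen after the data were seen. Every circRNA count at 1.5-fold and 2-fold stayed within 1.5 times its value under several alternatives. These were quantile, cyclic loess, equal-median and other percentile scaling, outlier spots kept and the median of spots. No detected mRNA probe past 1.5-fold after percentile scaling of the processed signals changed sign under any alternative tried. Gsta4, within 1.5-fold there, passed it under some alternatives and was negative after normexp with percentile scaling. The 12 circRNAs named in each direction were chosen for a constant direction, which 74.2% of detected circRNAs had. Normexp with percentile scaling gave 208 higher and 209 lower at 2-fold, 604 and 916 at 1.5-fold, and an SD of 0.43. Normexp with quantiles gave 212 and 209, 623 and 692, and 0.41. The authors' processed values gave 313 and 319 at 2-fold and 1007 lower at 1.5-fold. For normexp and the authors' values the cause was not tested. Scaling to bright corner spots gave 1109 and 273 at 2-fold and 3383 and 710 at 1.5-fold, since it moved the median log2 ratio to 0.31; normexp with percentile scaling moved it to -0.16. With no filter on detection 794 were 2-fold higher and 818 were 2-fold lower. The brighter circRNAs alone, 6293 in number, gave 257 and 279 at 2-fold and 669 and 747 at 1.5-fold, as fewer were counted. mRNA probes at 1.5-fold numbered 2 higher and 1 lower after normexp with percentile scaling, 0 lower after normexp with quantiles, and 10 higher and 1 lower with bright corner scaling. Numbers detected ranged from 12736 to 13720 on the control array and from 12793 to 13914 on the glyphosate array. Signal over background left 1038 circRNAs without a measurement on either array and 146 and 441 with at most a bound. Alternatives for host gene lists, classes, chromosomes and shared host genes were not run. No paired analysis was possible because each group had 1 array.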

Other observations

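Cyclic loess was fixed before the data were examined, the tests for stray spots and for background subtraction were set after the excess past 8-fold was seen but before their own values were, and the other tests in this part were chosen after the result was seen. Chgb and Gpi1 were higher on the glyphosate array at log2 ratios of 1.03 and 1.00. After scaling, their spots did not overlap between the arrays, with gaps of 0.80 and 0.87 on the log2 scale. Among the dimmer probes Ppara had a gap of 0.99. On the lower side, where signals were also low, the spots of Trp53rka were apart by 0.89. Those of Atg3 were apart by 0.39 and those of Taf1a by 0.17, while those of Tm9sf1 overlapped. The gaps of Atg3 and Taf1a rest on the scaling, as their spots overlapped between the arrays before it.

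The Mbp probe stood at a log2 ratio of 1.55. More linear RNA left after RNase R on the glyphosate array could raise mRNA probes in general. The other 35 had a median of 0.042 with an SD of 0.65, so they did not rise together. That cannot decide the question. Several of them, such as Il2 and E2f1, were dimmer on the glyphosate array than MM9NEGATIVE017, and whether a probe read linear RNA was not determined. Spot noise is argued against by a gap of 1.40 between the lowest glyphosate spot and the highest control spot. A larger oligodendrocyte share in the glyphosate pool may account for it but cannot be told apart from other causes, as 0 other listed oligodendrocyte markers were measured. Glyphosate exposure itself, a difference between pools and a difference between array runs stay open and untested.

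The 1097 circRNAs past 2-fold were far more than spot noise gave (mean 28.1). A brightness bias that varies with signal is argued against as the whole cause, since 1083 remained past 2-fold in number after cyclic loess. Differences of labelling, hybridisation and scanning that act probe by probe cannot be told apart from biology: the 14 control circRNA probes had an SD of 0.54 beside 0.61 for circRNAs, and none is known to report a constant amount of RNA. The differences may therefore be technical, biological or a mixture.

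Past 8-fold were 18 circRNAs higher and 8 lower among those detected on both arrays. Background subtraction as the whole cause is argued against by the authors' processed values, if these were made without it, as their lowest values make likely. Their exact method is unknown. They gave 11 higher and 0 lower for these circRNAs, and 11 and 3 over all circRNAs. Stray bright spots stay open, since 0 of 655 repeated spots stood 8-fold above their probe's median, which still allows up to 57.6 such circRNAs. The filter on detection may also account for part of the excess, which stays open as the values diverge: with circRNAs detected on at least 1 array there were 29 higher and 26 lower from measured signals, but 20 and 12, a ratio of 1.67, with the dim array at its floor. Higher outnumbered lower in the other settings too, with 5 and 0 after either normexp setting, 27 and 4 with bright corner scaling and 12 and 2 among the brighter circRNAs, but as its size varied and rests on few circRNAs, no preferred direction is read from it.

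ASCRP4002683 and ASCRP4002684, at background on the glyphosate array, carry adjacent identifiers, but their spots lay in rows 24 and 48 of the array. The 77 detected circRNAs within 3 rows and 3 columns of these spots had a median log2 ratio of -0.13 (SD 0.62). Over 12205 pairs of adjacent identifiers, 76 were past 2-fold in the same direction and 60 in opposite directions. Shuffled identifiers gave a mean of 67.4 pairs in the same direction, with 95 percent of 10000 shuffles between 52 and 83. No biological explanation was tested for the pair.

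Of 15 custom probes of the array design, whose targets the files do not name, 14 were well above background on every spot of both arrays. Their log2 ratios ran from -2.27 to 0.11, and 1 was at least 1.5-fold lower.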
